A study of Arabidopsis thaliana with 8 samples.

How the data were processed

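Gene expression was measured in 12-day-old seedlings of Arabidopsis thaliana (accession Columbia) with 8 one-colour Agilent oligonucleotide arrays. The seedlings carried either the empty pTA vector or pTA-ANAC096, and were grown in liquid MS medium at 23 °C with 16 h of light and 8 h of dark. ANAC096 is a transcription factor of the plant NAC family, and dexamethasone is the steroid generally used to switch on transgenes in pTA vectors. Dexamethasone at 30 µM was given to every group for 1 h. In the groups with abscisic acid (ABA, the plant hormone of drought and osmotic stress), 2 µM ABA was present for the last 30 min of that hour. The 4 groups of 2 arrays are called control (empty vector, dexamethasone), ANAC096 (ANAC096 line, dexamethasone), ABA (empty vector, dexamethasone and ABA) and ANAC096+ABA (ANAC096 line, dexamethasone and ABA). Groups and replicate numbers were taken from the sample titles, and the series' design text speaks of 2 biological replicates per condition. No detail on how the replicates were grown or pooled is given in the sources used here, so p-values measure the spread between these arrays.

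The authors deposited 1 scanner output per array, with spot intensity values on a linear scale. Per the file headers, these intensities were extracted by Feature Extraction 10.7.1.1 with protocol GE1_107_Sep09 on array design 031025. All 8 arrays lay on 1 slide and were read in 1 scan. Slide row 1 held the 4 arrays without ABA and slide row 2 the 4 arrays with ABA, while slide columns separated the lines, so neither row nor column can be separated from the treatment or the line it coincides with. Columns of the deposited scanner files that are flags, marked there as 0 or 1, gave for each spot whether it was well above background, saturated or an outlier. The authors also deposited a table of log2 values. Quantile normalization of the log2 median signals over all 62976 spots, with no background correction, returned all 8 columns of that table within 1e-08, the largest difference being 5.0e-09, and the column medians were 10.26 to 10.27. The direction and scale of that table are therefore settled from the values, and it served as an alternative.

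For the main values, log2 of the background-subtracted processed signal was taken, and each array's 75th percentile of it was subtracted. The 1319 control spots and spots marked as outliers (376 to 1230 per array) were left out. Spots of a probe were averaged: 25549 probes had 1 spot and 18054 had 2. A probe was tested if it was well above background on both arrays of at least 1 group, which kept 34503 of 43603 probes (79.1%). Group means of all 8 arrays were fitted with limma 3.58.1 in R 4.3.3 with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The fit had 4 residual degrees of freedom and a prior of 1.99. Standard errors of log2 differences come from that fit, and the number of arrays limits their precision. The comparisons were each single treatment against control, and both together against control and against each single treatment. Also fitted were the difference of the ABA effect between the lines (the interaction), and the average effects of the ANAC096 line and of ABA. The ANAC096 line is called a treatment here for short. Every array had dexamethasone, so line differences present before it cannot be told apart from the effect of inducing ANAC096. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.33, so single-probe p-values rest on the limma model. On simulated data for ANAC096 against control, with 200 of 34503 probes changed, 53% of changes of 0.5 on the log2 scale and 79% of changes of 1 were called, with 6 false calls. On the measured arrays 59.2% of probes were called in this comparison, so the adjusted threshold was stricter in the simulation. These shares and the false calls therefore do not carry over to the measured arrays.

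A probe below background on both arrays of a group has only a bound there. Its change is given as at least so many fold, with the brighter group's mean set against, per array, the higher of the dim probe's own signal and the lowest signal among probes well above background. Changes without "at least" are between groups in which the probe was well above background on both arrays, except where stated. Counts of called probes include both kinds.

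The scanner files name probes by an identifier of the array maker and do not pair them with genes, and the reference table used here held 0 of these identifiers. The 25 gene lists, the gene set tests and the ANAC096 and marker genes fixed before the data were examined were therefore not analysed here, nor was the mean over the probes of a gene. The fixed rule for naming items, the largest changes past the threshold with both arrays of 1 group above both of the other and the probe well above background on all arrays of both groups, was limited to the 2 largest rises and 2 largest falls of ANAC096 against control. Which of the probes detect the transgene or the native ANAC096 transcript was not analysed here.

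Replicate arrays correlated at Pearson r 0.9963 to 0.9979 across tested probes, which are not independent replicates, against 0.9584 to 0.9822 between arrays of different groups. The same spot differed between replicate arrays with a robust SD of 0.144 in control on the log2 scale. It was 0.106 in ANAC096, 0.0697 in ABA and 0.0983 in ANAC096+ABA. Between the 2 spots of a probe on 1 array it was 0.122 to 0.152. The replicate differences of those 2 spots correlated at r 0.09 (ABA) to 0.49 (control) over 13247 probes. Spot noise alone would give 0, and each array was counted as 1 replicate. The fit gives each probe 1 spread for all groups, so its standard errors do not show that the control pair differed most. Alternatives were normexp background correction with an offset of 50 on the median signals (the scanner files hold no mean signal), quantile normalization, the authors' table, other filters on dim probes, other variance settings, other thresholds, the replicate number as a block, fits of 2 groups alone and leaving out each array in turn. Scaling each array to 7 E1A spike-in probes, which detect RNA added to each sample in a fixed amount by the array maker's protocol, was added after seeing the data.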

Results

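Seedlings with a dexamethasone-inducible ANAC096 construct and seedlings with the empty vector were compared with and without 30 min of ABA, with 2 arrays in each of the 4 groups. On each array, 32732 to 34814 of 43603 probes were well above background and 0 spots were saturated. The 75th percentile of the processed signal was 5252 to 8128. Arrays with ABA, which lay in the other slide row, had fewer probes well above background (75.07% to 75.94%) than arrays without ABA (77.77% to 79.84%), and their negative-control signal was higher (9.78 to 11.7 against 5.89 to 7.47). Groups differed more than replicates: the first 3 principal components held 53.7%, 24% and 14.4% of the variance, and the next held 2.54%.

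All changes are relative to the 75th percentile of each array, and the E1A spike-ins did not stay level on that scale. Their mean log2 level was 0.06 ± 0.02 in control, 0.69 ± 0.09 in ANAC096, 0.31 ± 0.05 in ABA and -0.04 ± 0.18 in ANAC096+ABA (SD, n = 2). Scaling to the spike-ins instead moved the median of all probes by -0.63 for ANAC096 against control, -0.26 for ABA against control and 0.1 for ANAC096+ABA against control. It moved the median by 0.36 for ANAC096+ABA against ABA, 0.73 for ANAC096+ABA against ANAC096 and 0.99 for the interaction. Balances at any fold and at 2-fold are therefore given on both scales. Counts beyond 8-fold and overlaps in each paragraph are on the 75th percentile scale, with the other scale given last.

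**Figure D1:**
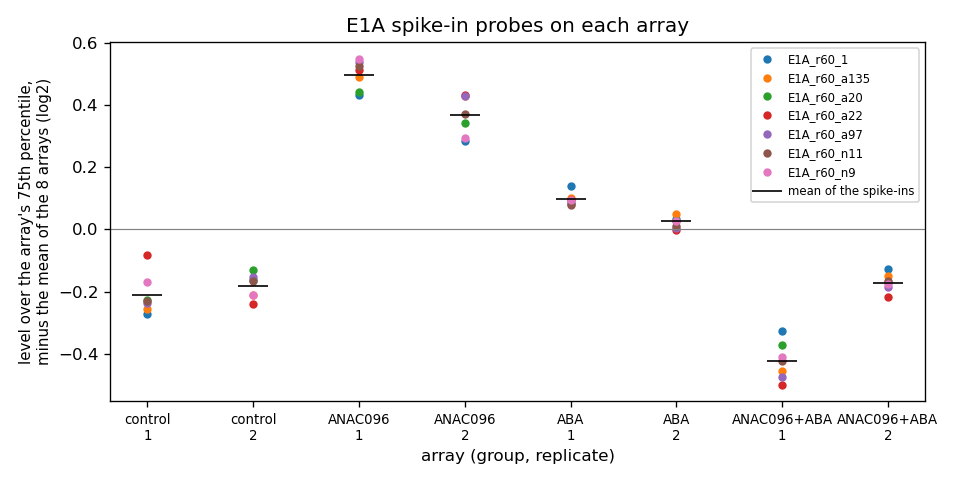
Level of each of the 7 E1A spike-in probes (points) and their mean (bars) on the 8 arrays, in log2 units over the array's 75th percentile after subtracting the mean of the 8 arrays. Both ANAC096 arrays lie highest, and the 2 ANAC096+ABA arrays lie below the ABA arrays.

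The first comparison asked which transcripts differed in the ANAC096 line without ABA. Of 34503 tested probes, 2443 were at least 2-fold higher in ANAC096 than in control and 819 at least 2-fold lower at an adjusted p under 0.05. The median log2 change was 1.48 among the higher and -1.28 among the lower probes, against a median standard error of 0.0684. At least 8-fold changes comprised 183 probes higher and 28 lower. Without a minimum fold, limma called 9191 probes higher and 11243 lower, together 59.2% of those tested. No filter on dim probes turned this balance, to 11131 higher and 10661 lower. With spike-in scaling 2548 were called higher and 25769 lower, and the balance at 2-fold turned to 995 higher and 6980 lower. The 819 lower probes became 412 with normexp background correction.

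Among probes measured in both groups, A_84_P21604 rose furthest, by 6.99 on the log2 scale (128-fold, SE 0.08, adjusted p 6.0e-07), from -4 ± 0.06 in control to 3 ± 0.05 in ANAC096 (mean log2 level ± SD, n = 2). A_84_P787940 rose by 6.94 (123-fold, SE 0.17, adjusted p 2.3e-06), from -7.46 ± 0.17 to -0.52 ± 0.06. This rise was 5.61 with normexp correction and 5.57 in the authors' table. The control level of this probe was near background, as its level of -7.59 in ABA was not well above background. A_84_P761415 fell by 5.57 (47.7-fold, SE 0.04, adjusted p 3.7e-07), from -0.78 ± 0.01 to -6.36 ± 0.04, the log2 change being -4.52 with normexp correction and -4.78 in the authors' table. A_84_P11480 fell by 4.38 (20.9-fold, SE 0.06, adjusted p 7.3e-07), from 1.03 ± 0.07 to -3.35 ± 0.06. The files pair none of these probes with a gene. A further 210 called probes were above background on both ANAC096 arrays and on no control array, 178 of them at least 2-fold by this bound and the largest at least 136-fold. In the opposite direction, 209 probes were above background in control and on no ANAC096 array, 63 of them at least 2-fold by the bound and the largest fall at least 13.8-fold.

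**Figure D2:**
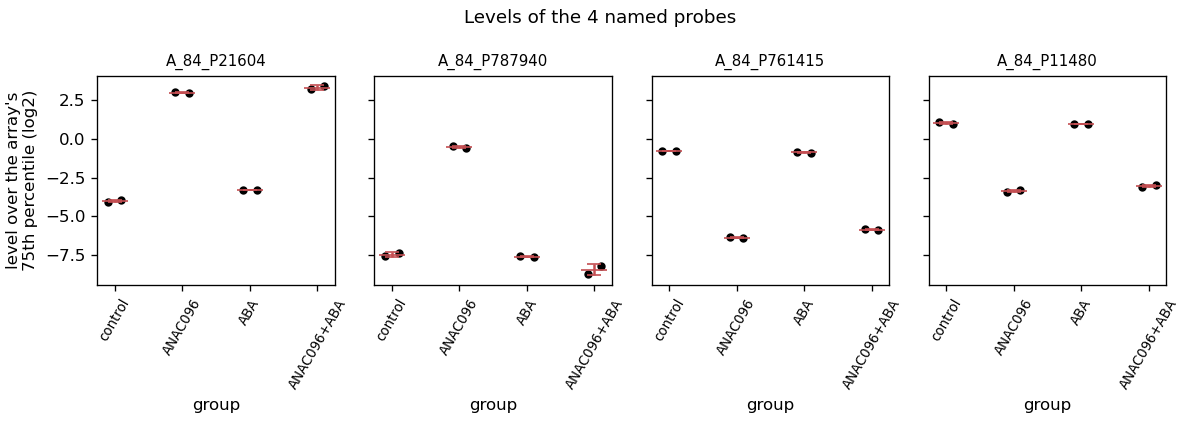
Log2 level over the array's 75th percentile of the 4 named probes on each array (black points), with the group mean and SD (red, n = 2). A_84_P21604 lies at 3 and 3.31 in the groups of the ANAC096 line, whereas A_84_P787940 is high in ANAC096 without ABA and not well above background in either group with ABA.

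ABA against control asked how the empty vector line differed after 30 min of the hormone. With ABA, 1460 probes were at least 2-fold higher and 638 lower, with median log2 changes of 1.51 and -1.29, and 113 rose and 16 fell at least 8-fold. The lower probes numbered 272 with normexp correction, 317 in the authors' table and 395 among probes well above background on all 8 arrays. Among probes measured in both groups, the furthest rise was 46.7-fold and the furthest fall 49.3-fold. Of the called probes, 329 were above background in control and on no ABA array, 46 of them at least 2-fold lower by the bound. In the opposite direction there were 66, of which 65 were at least 2-fold higher by the bound. No array was taken before ABA, so how much of these differences arose within the 30 min was not tested. Of the named probes measured in both groups, none moved far. A_84_P21604 rose by 0.68 (SE 0.08, adjusted p 9.7e-04). The log2 differences of A_84_P761415 and A_84_P11480 were -0.08 and -0.07 (limma adjusted p 1.8e-01 and 3.6e-01). A_84_P787940 was not well above background on any ABA array, so its difference has no measured size. Its signals gave -0.13 (limma adjusted p 5.5e-01), 0.26 with normexp correction and -0.38, past the threshold, with spike-in scaling. At any fold, limma called 6390 probes higher and 9891 lower, 16281 in all, and 10576 when ABA replicate 1 was left out. With spike-in scaling 2904 probes were called higher and 15114 lower, and 1043 were at least 2-fold higher and 1421 lower. Slide row and ABA cannot be told apart in this comparison.

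**Figure D3:**
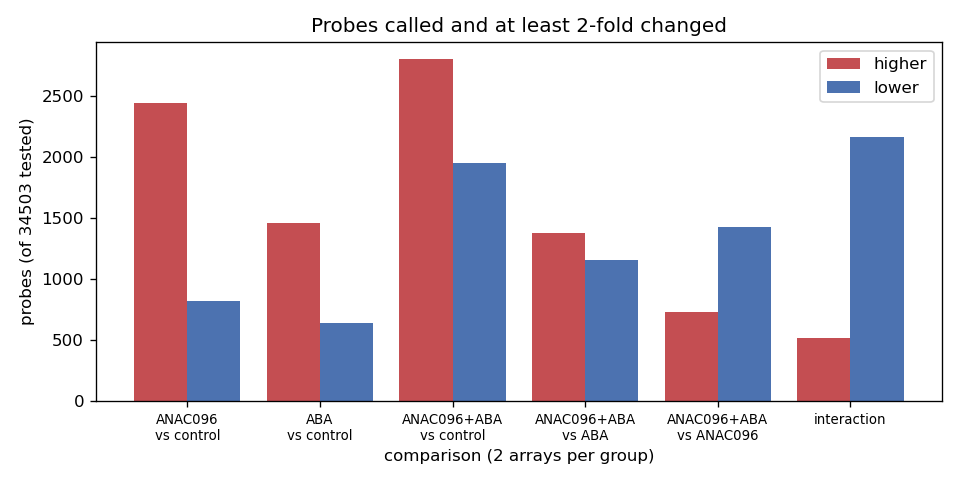
Number of probes at least 2-fold higher (red) or lower (blue) at an adjusted p under 0.05 in 6 comparisons, of 34503 tested, scaled to the 75th percentile. Higher probes outnumber lower ones against control, 2443 to 819 for ANAC096 and 1460 to 638 for ABA, but with spike-in scaling these balances turn to 995 against 6980 and 1043 against 1421, as do those of ANAC096+ABA against ANAC096 (6529 to 547) and of the interaction (18547 to 600).

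With ABA present, the ANAC096 line differed from the empty vector line at 2533 probes by at least 2-fold, 1374 higher and 1159 lower. These arrays shared 1 slide row, as did ANAC096 and control. The lines lay in different slide columns, so column and line cannot be told apart in either comparison. The large changes of A_84_P21604 (higher by 6.62, SE 0.08, adjusted p 1.4e-06), A_84_P761415 (lower, -4.98, SE 0.04, adjusted p 1.1e-06) and A_84_P11480 (lower, -3.99, SE 0.06, adjusted p 1.6e-06) were present with ABA too. The rise of A_84_P787940 was not seen with ABA: it was not well above background in either group, so its change has no measured size. Beyond 8-fold, 35 probes were higher, against 183 without ABA, and 43 were lower, against 28. Across the 34503 probes, the line's effect without ABA and its effect with ABA correlated at Pearson r 0.44 and Spearman rho 0.39, from arrays that the 2 effects do not share. Higher at least 2-fold under both conditions were 801 probes, against 97.3 for independent lists, and 292 were lower under both, against 27.5. Another 122 probes were higher without ABA and lower with it, against 82.1, and 6 changed the other way, against 32.6. At any fold 7590 probes were called higher and 7789 lower, and 6935 and 6873 with no filter on dim probes. Some fits that left out 1 array turned this balance too. With spike-in scaling these became 15536 and 1941, with 2945 higher and 621 lower at 2-fold. Normexp background correction gave 1653 probes at 2-fold, 879 of them higher. The log2 change of A_84_P761415 was -4.22 with normexp correction and -4.29 in the authors' table.

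In the ANAC096 line, scaled to the 75th percentile, more probes were at least 2-fold lower than higher with ABA. Against ANAC096, 728 probes were at least 2-fold higher in ANAC096+ABA and 1428 lower, with 18 and 130 beyond 8-fold. The lower probes numbered 932 in the authors' table. A_84_P787940 was among those lower with ABA: it was not well above background on any ANAC096+ABA array, so its level was at least 116-fold lower than in ANAC096 on the main scale (adjusted p 2.7e-06). The log2 difference was -5.65 with normexp correction and -5.85 in the authors' table, which are smaller than this bound. In all, 491 called probes were above background in ANAC096 and on no ANAC096+ABA array, 200 of them at least 2-fold lower by the bound. In the opposite direction there were 48, of which 38 were at least 2-fold higher by the bound. At any fold 7641 probes were called higher and 7931 lower, a balance that other settings turned. Quantile normalization gave 8569 higher and 7144 lower, the authors' own values 9002 and 7835, no filter on dim probes 9016 and 7389, and probes well above background on all 8 arrays 7597 and 7424. Without ANAC096 replicate 1 it was 5921 and 5721. With spike-in scaling both balances turned, to 28719 higher and 1287 lower, and at 2-fold to 6529 higher and 547 lower. The ABA effects in the lines correlated at r 0.32 (rho 0.23) across probes, again from separate arrays. Of the 1460 probes raised by ABA in the empty vector line, 406 (27.8%) were also raised at least 2-fold in the ANAC096 line, against 30.8 for independent lists. Of the 638 lowered probes, 237 (37.1%) were lowered in both, against 26.4. Raised in the empty vector line but lowered in the ANAC096 line were 65 probes, against 60.4, and 7 changed the other way, against 13.5. Row and ABA coincide in both of these ABA effects.

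Scaled to the 75th percentile, ANAC096+ABA had the most probes changed against control. In that comparison 2800 probes were at least 2-fold higher and 1953 lower, and 333 and 92 changed at least 8-fold. The furthest measured changes were a 164-fold rise and a 54.2-fold fall. A_84_P21604 was higher by 7.31 (SE 0.08, adjusted p 1.4e-07), while A_84_P761415 and A_84_P11480 were lower, by log2 values of -5.06 and -4.06 (SE 0.04 and 0.06, adjusted p 9.3e-08 and 2.2e-07). A_84_P787940 was not well above background on any ANAC096+ABA array, so its change has no measured size: the signals gave -0.99, and -0.05 with normexp correction. A total of 629 called probes were above background in control and on no ANAC096+ABA array. By the bound 169 of them were at least 2-fold lower, the largest fall being at least 79.3-fold. In the opposite direction there were 150 such probes, 148 of them at least 2-fold higher by the bound and the largest at least 136-fold. The 1953 lower probes became 1207 with normexp correction and 1299 in the authors' table, and the log2 change of A_84_P761415 became -4.32 and -4.36. At any fold 8479 probes were called higher and 12706 lower, 61.4% of those tested. With spike-in scaling 7746 were higher and 6108 lower, and at 2-fold 3253 higher and 1694 lower, 4947 in all. That is fewer than the 7975 of ANAC096 against control on the same scale, so the order of these comparisons by count turned.

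Averaged over ABA, the ANAC096 line was at least 2-fold higher at 1570 probes and lower at 629, and averaged over the lines, ABA raised 880 and lowered 753. At any fold the line had 9078 probes higher and 11284 lower, and ABA 6847 higher and 9845 lower, which spike-in scaling changed to 5137 and 12762 for the line and turned to 12645 and 2568 for ABA. No filter on dim probes also turned the balance for ABA, to 9661 higher and 9257 lower. At 2-fold spike-in scaling gave 1269 higher and 891 lower for the line, and 1456 higher and 481 lower for ABA. The counts at 2-fold were 2199 for the line and 1633 for ABA, against 1400 and 1037 with normexp correction and 1429 and 1081 in the authors' table. With normexp correction the line had 1062 probes higher and 338 lower, and ABA 658 higher and 379 lower. In the authors' table these were 1039 and 390, and 684 and 397, and among probes well above background on all 8 arrays ABA had 733 higher and 441 lower.

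The interaction asked whether the ABA effect differed between the lines. The ABA effect was at least 2-fold lower in the ANAC096 line than in the empty vector line for 2163 probes and at least 2-fold higher for 517, and 14492 probes (42%) were called at any fold, 8000 higher and 6492 lower. Beyond 8-fold, 185 were lower and 15 higher. The 517 higher probes became 180 with normexp correction and 300 in the authors' table. A_84_P787940 was called lower, but its interaction has no measured size, because it was below background in both groups with ABA: the signals gave -7.8, against -5.91 with normexp correction and -5.79 in the authors' table. The interactions of A_84_P761415 and A_84_P11480 were 0.59 and 0.39 (SE 0.06 and 0.08, adjusted p 1.0e-03 and 1.3e-02), and 1.58 and 1.38 with spike-in scaling. That of A_84_P21604 was -0.37 (SE 0.11, adjusted p 4.0e-02), but 0.61 with spike-in scaling, and it missed the threshold in 6 of the 8 fits that left out 1 array and with no filter on dim probes (adjusted p 0.0615). Without ABA replicate 1, the interaction of A_84_P11480 was 0.39 with an adjusted p of 0.0504 in limma. At any fold the balance was 7161 higher and 7727 lower with normexp correction and 6842 and 6824 with no filter on dim probes. The direction of the interaction across probes depended on the scaling: with spike-ins 28657 probes were called higher and 1121 lower, 18547 probes were at least 2-fold higher and 600 lower, and 60.7% of the 2680 probes changed at least 2-fold were still called in the same direction. Without ABA replicate 1, 9508 probes were called.

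ANAC096 without ABA and ABA in the empty vector line changed many of the same probes. Of the 1460 probes raised by ABA at least 2-fold, 1000 (68.5%) were also at least 2-fold higher in ANAC096, against 103 for independent lists. Of the 638 lowered by ABA, 200 (31.3%) were also lower in ANAC096, against 15.1. Opposite changes were few: 39 probes were higher in ANAC096 and lower with ABA, against 45.2, and 6 changed the other way, against 34.7. Both changes share the control arrays. Their log2 changes correlated at r 0.63 (rho 0.6), and unchanged groups simulated against shared controls gave a median r of 0.5. The covariance was 0.25, against a simulated median of 0.0138 and a highest simulated value of 0.0167 in 100 draws. Part of the excess overlap may come from the shared controls. The average effects of line and ABA correlated at r 0.41. Control enters both of them with the same sign, and its errors cancel only where all groups have the same spread, as in the simulation (highest r 0.06). On the measured arrays the control replicates differed most, with a robust SD of 0.144 against 0.0697 to 0.106 in the other groups. Higher in both averages were 494 probes, against 40 for independent lists, and 138 were lower in both, against 13.7. In the opposite directions 78 were higher with the line and lower with ABA, against 34.3, and 7 changed the other way, against 16.

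**Figure D4:**
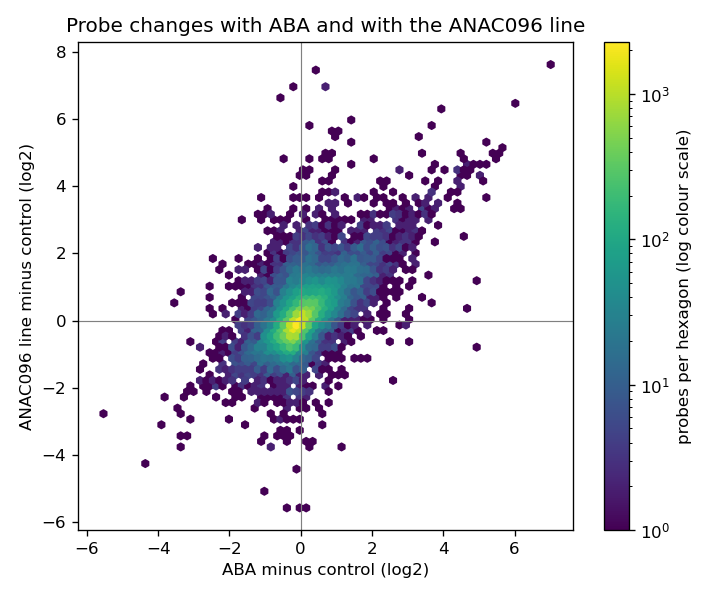
Log2 change of each tested probe in ANAC096 against control (vertical) and in ABA against control (horizontal), with colour for the number of probes per hexagon on a log scale. The cloud runs from lower left to upper right (r 0.63), and both axes share the control arrays.

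Combined treatment moved most of these shared probes by less than the sum of the single log2 changes. Whether the changes add up on the linear scale was not tested. For the 1000 probes raised by each alone, the median log2 change was 1.69 with ANAC096, 1.68 with ABA and 2.28 with both, where the single changes added up to a median of 3.38. The interaction was called lower for 868 of them and higher for 12. These probes were chosen by their single changes, which favours an interaction against their direction. In simulated groups with exactly additive effects, limma called 0 interactions among 1053 such raised probes, with an unadjusted p under 0.05 for 55 lower and 19 higher interactions, and 0 among 254 lowered ones, with 3 lower and 44 higher. No simulated probe had an interaction, which makes the adjusted threshold stricter than on the measured arrays, so these 0 counts are no like comparison. On the measured arrays, 592 of the raised probes (59.2%) were called above each single treatment when both were combined, and 76 were below each. For the 200 probes lowered by each alone, the medians were -1.37, -1.5 and -1.92, against a sum of -2.96. The interaction was higher for 145 and lower for 10, and 87 (43.5%) lay below each single treatment. With spike-in scaling, 499 probes were raised by each alone, with the interaction lower for 277 and higher for 30. That scaling gave 923 probes lowered by each alone, with the interaction higher for 872 and lower for 9. Over all 34503 tested probes it called the interaction higher for 28657 and lower for 1121.

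**Figure D5:**
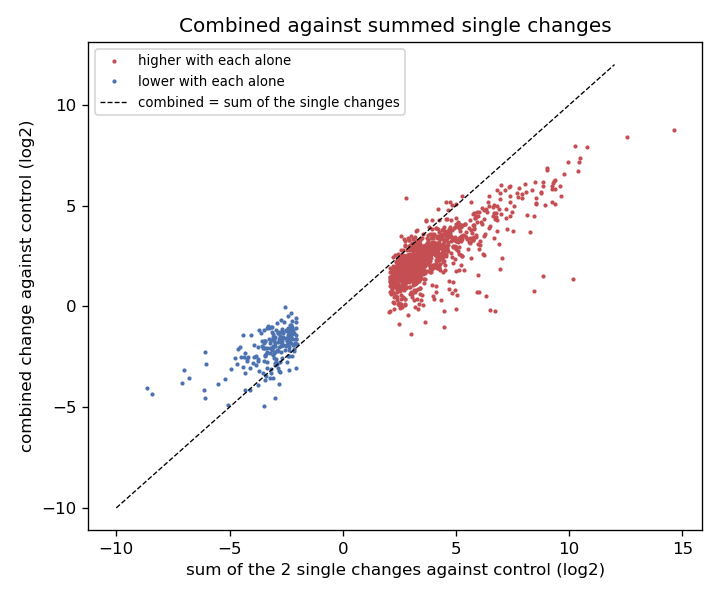
Log2 change with ANAC096+ABA against control (vertical) over the sum of the changes with ANAC096 and with ABA (horizontal), for the 1000 probes at least 2-fold higher with each alone (red) and the 200 lower with each alone (blue), scaled to the 75th percentile. Most red points lie below the dashed line of equality, and with spike-in scaling 277 of 499 such probes had a lower interaction.

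Other probes passed 2-fold against control only when both treatments were combined. There were 916 such probes higher, with median log2 changes of 0.62 with ANAC096, 0.53 with ABA and 1.24 with both, against a sum of 1.06. The interaction was called higher for 370 and lower for 94. Among the 1003 that were lower, the medians were -0.43, -0.45 and -1.26, against a sum of -0.86, and the interaction was called lower for 534 and higher for 79. These probes were chosen by their combined change, which favours an interaction in its direction. In simulated groups with exactly additive effects, limma called 0 interactions among 1723 such higher and 1935 such lower probes, with an unadjusted p under 0.05 for 62 higher and 17 lower interactions in the former and 39 and 60 in the latter. No simulated probe had an interaction, which makes the adjusted threshold stricter than on the measured arrays, so these 0 counts are no like comparison. With spike-in scaling there were 2011 such probes higher, the interaction being higher for 1661 and lower for 5. There were 365 lower, the interaction being lower for 190 and higher for 31. Over all 34503 tested probes that scaling called the interaction higher for 28657 and lower for 1121, so higher interactions were not particular to these probes.

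With spike-in scaling, the counts of probes at least 8-fold higher and lower were 94 and 60 for ANAC096 against control, 83 and 22 for ABA against control, and 375 and 77 for ANAC096+ABA against control. They were 58 and 24 for ANAC096+ABA against ABA, 61 and 69 for ANAC096+ABA against ANAC096, and 73 and 77 for the interaction, so that the balance turned for ANAC096+ABA against ABA and came close to even for the last 2. On this scale 746 probes were raised and 149 lowered by ABA in both lines, against 197 and 22.5 for independent lists. The line's effect was shared without and with ABA by 581 higher and 282 lower probes, against 84.9 and 126. ANAC096 and ABA against control shared 499 higher and 923 lower probes, against 30.1 and 287. The average effects shared 552 higher and 130 lower probes, against 53.6 and 12.4.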

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

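The tests of slide row, of the spike-ins and of the 75th percentile scaling were chosen after the results were seen. The ABA effect differed between the 2 lines, by a test of the difference itself, at 14492 probes, and by at least 2-fold at 2680. The 4 named probes, chosen by their change in ANAC096 against control, which is itself a part of the interaction, passed the same test: -0.37 (A_84_P21604, 0.61 with spike-in scaling), 0.59 (A_84_P761415) and 0.39 (A_84_P11480). For A_84_P787940 the signals gave -7.8, but it was below background in both groups with ABA, so that this is no measured size, and normexp correction gave -5.91.

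The difference between arrays with and without ABA may come from the hormone or from the slide row, since every ABA array lay in row 2. A row that adds the same difference in both lines would leave few interactions, and 42% of tested probes had one, so such a row cannot account for the whole difference. For the 643 probes that changed at least 2-fold the same way in both lines, row and ABA cannot be told apart, because the design has no ABA array in row 1. A row effect that itself differed between slide columns was not tested.

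In ANAC096 against control more probes were called lower than higher, 11243 against 9191, although higher probes prevailed at 2-fold. The balance depends on the processing: the share of higher calls was 49.6% with normexp correction, 51.1% with no filter on dim probes, 40.7% with quantile normalization and 9% with spike-in scaling, so whether scaling to the 75th percentile shapes it stays open. The E1A spike-ins lay higher in ANAC096 by 0.63 on the same log2 scale, with an SD over the 7 spike-ins of 0.05. A larger amount of added spike-in, a smaller amount of labelled seedling RNA per sample and a lower total of many transcripts would each give that value, and these cannot be told apart without a record of the RNA amounts. The direction of the interaction stays open with it, since the spike-ins alone carried an interaction of -0.99.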

How the results depend on the processing

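Spike-in scaling was chosen after seeing the data; all other alternatives were fixed before the data were examined. With it, ANAC096 against control had 7975 probes at 2-fold (3262 with the main scaling), ANAC096+ABA against control 13854 called (21185), ANAC096+ABA against ANAC096 30006 called (15572) and 7076 at 2-fold (2156), and the interaction 29778 called (14492) and 19147 at 2-fold (2680). The interaction of A_84_P21604 reversed to 0.61. This scaling shifts all probes of a comparison together, but the cause of each change in a count was not tested. Normexp correction gave 1653 probes at 2-fold for ANAC096+ABA against ABA, 1400 for the average line effect and 1037 for the average ABA effect, and the authors' table gave 1429 and 1081 for these averages; the cause was not tested. The spread of a correlation of effects was its SD over 16 choices of arrays. It was 0.04 for the ABA effects in the lines, 0.029 for the line effects and 0.009 for the average effects. The lowest r over these choices was 0.23, 0.36 and 0.38. The choices reuse the same arrays, so this SD is no sampling error. Apart from fits without 1 array, the correlation of the line effect without and with ABA moved by more than its spread (0.36 with no filter on dim probes). So did that of the average effects (0.46 with normexp, 0.45 in the authors' table, 0.35 with no filter, 0.46 with probes bright on all 8 arrays). The cause was not tested.

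Requiring 2-fold besides the adjusted p lowered the counts, by construction, to 3262 (ANAC096 against control), 2098 (ABA against control), 4753 (ANAC096+ABA against control), 2533 (against ABA), 2156 (against ANAC096), 2680 (interaction), 2199 (average line effect) and 1633 (average ABA effect). With an unadjusted p these were 3305, 2157, 4791, 2586, 2217, 2835, 2225 and 1658.

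Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 10576 to 16152 calls for ABA against control and 9508 to 15493 for the interaction, both lowest without ABA replicate 1. The correlations ranged from 0.27 to 0.34 for the ABA effects in the lines, 0.41 to 0.45 for the line effects and 0.39 to 0.42 for the average effects. The first 2 moved by more than their spread without control replicate 2 (0.27 and 0.41), and the third in 6 of the 8 fits. ANAC096 against control had 17012 to 20067 calls. The interaction of A_84_P21604 missed the threshold without control replicate 1, either ANAC096 replicate, either ABA replicate or ANAC096+ABA replicate 1 (adjusted p 0.067 to 0.107), with log2 values of -0.27 to -0.41.

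No pairing by replicate number was seen in the values: deviations of same-numbered arrays correlated at -0.09 to 0.063 over 6 pairs of groups. This does not show how same-numbered samples were grown or processed. With the replicate number as a block, ANAC096 against control had 19503 calls, ABA against control 15177 and the interaction 13277, and no count moved by over 1.5 times. Of the values of the named probes under all alternatives, 381 kept their direction and side of the threshold, 14 lost the threshold, 1 gained it and 2 reversed, the second being A_84_P787940 in ABA against control (-0.13, and 0.26 with normexp, neither past the threshold; the cause was not tested). The mean over the probes of a gene and the gene set tests were not run, because probes could not be assigned to genes. Signal over background limited the dim probes, such as A_84_P787940 with ABA, to bounds.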

Other observations

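Some probes stood apart in 1 group alone. In control, 912 probes were at least 2-fold lower than in each of the other 3 groups and 186 higher. In ANAC096 without ABA, 349 probes were at least 2-fold higher than in each other group and 24 lower, and 90 of the higher ones exceeded 4-fold. ANAC096+ABA had 343 probes higher and 481 lower than in each other group, and ABA had 49 higher and 49 lower. These counts were made after seeing the data, on the 75th percentile scale. With spike-in scaling, control had 466 probes lower and 575 higher than each other group, ANAC096 164 higher and 599 lower, ANAC096+ABA 1462 higher and 205 lower, and ABA 40 higher and 93 lower, so which direction prevailed in a group changed with the scaling in control, ANAC096 and ANAC096+ABA.

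The ANAC096 line without ABA and ABA in the empty vector line moved many of the same probes, and a candidate explanation is that the line alone already holds part of the hormone response. Shared control arrays alone gave a covariance of at most 0.0167 in the simulation, against 0.25 observed. The simulation gave all groups the same spread, whereas the control replicates differed most, so the simulated value may be too low. A control group that stood apart for another reason, with the other groups at 1 level, would leave few probes beyond both single treatments. Of the raised probes 59.2% lay above each, so this strict form cannot account for the whole of their change. Of all tested probes, however, 44.6% were called between ANAC096+ABA and ABA and 45.1% between ANAC096+ABA and ANAC096. The share therefore cannot decide about a control group that stood apart beside other differences between the groups. The step beyond the higher single treatment was small, with a median log2 of 0.4 (first quartile -0.04) beside single changes of 1.69 and 1.68. A control group standing apart may thus still account for most of the change of the raised probes. For the lowered probes 43.5% lay below each, short of the 50% set in advance. Alternatives fell on both sides of it, from 35.7% without ANAC096+ABA replicate 1 to 63.4% with normexp correction, so for these a control group standing apart cannot be told apart from a shared response. Spike-in scaling gave 79.6% for the raised and 11.1% for the lowered probes. It shifts all probes of a comparison alike, however, and is no independent evidence on either share or on the step. Such a shared response remains a hypothesis found and tested on the same arrays, and no named ABA genes were analysed here to test it.

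Of the 35 splits of the 8 arrays into 4 and 4, a 2-group limma fit called 6627 probes for the ANAC096 line and at most 1700 for any other split, so 1 split reached the real count. For ABA the real split called 1700 and 2 splits reached that count, the other being the split by line, a structure of the samples that the design contains. No split that parts replicate arrays reached either count. The splits that keep replicate arrays together are only 3, with 6627, 1700 and 62 calls, too few for a share under 0.05.

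The control probe ERCC-00104_60 was well above background on 21 and 18 of its 35 spots on the control arrays, 8 and 7 on the ANAC096 arrays, 1 and 3 on the ABA arrays and 4 and 2 on the ANAC096+ABA arrays.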
